A study of Mus musculus with 6 samples.

How the data were processed

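Liver total RNA of male C57BL/6 mice on 2 diets was measured on 6 Affymetrix Mouse Gene 1.0 ST arrays, 3 per diet. Per the labels' protocols, RNA was extracted with Trizol, and the series design names Partek Genomics Suite and cyberT for differential expression. The deposited values are probe set intensities on a linear scale. The background correction, normalisation and summary method behind them are not given in the sources used here. The near-equal medians of the 6 arrays (158 to 163) leave open whether a normalisation between arrays was applied by the authors. Groups were taken from the labels' source names. No pair of arrays held the same values: at most 28 of 35556 probe sets were identical between 2 arrays.

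Of 35556 probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 several and 12146 none. Symbols were looked up by gene identifier in a RefSeq gene table, where 21698 of the single-gene probe sets matched and 0 symbols needed an update. Genes were tested on single-gene probe sets only, and for the 998 genes with more than 1 such probe set, the one with the highest mean was used, which left 19937 genes. No genome coordinates were used. Genes with near-identical copies, among them the Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Ugt2b, Hsd3b, Ces1, Saa and Gsta families, are uncertain because related transcripts can bind the same probes.

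Values were taken as log2(intensity + 1), since the deposited intensities were linear, and the diets were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Adjusted p-values in the text are limma's unless said otherwise. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. Fold changes on this scale understate the change of dim genes, and the number of arrays limits the precision.

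Before the data were examined, 35 gene lists were fixed (22 pathway lists and 13 of cell type or zonation markers), with 610 memberships measured and 88 not, 37 of these on probe sets of several genes only. Each list was tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 35 lists, and again with the correlation estimated from each list. With the preset correlation 15 lists were called, 8 higher and 7 lower. With the estimated one 1 was called, and 9 had an unadjusted p under 0.05. The result of 1 pathway list, which was not called, is not reported here. The lists are bulk liver markers and classify no cell.

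The genes named in the text were chosen by a rule fixed in advance: 20 genes of sterol metabolism and autophagy, of which 17 were measured and are reported, the 12 highest and 12 lowest fold changes among genes past the threshold whose groups did not overlap, and in each list up to 4 members past the threshold with the largest change, or 1 or 2 with the smallest p where none passed. Other genes belong to the test sets of the closing section or are said to have been chosen after their values were seen.

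The alternatives were a block for the replicate number, quantile normalisation, centring on array medians, leaving out the dimmest 33.3% of genes, the mean of a gene's probe sets, limma with an intensity trend and robust prior, a regularised test in the manner of cyberT whose settings in the study are not given, pseudocounts of 16 and none, every probe set, a 1.5-fold limit and leaving out each array in turn. Every probe set and the 1.5-fold limit were applied to the counts of genes past the threshold only, so statements on single genes and lists over all alternatives leave these out. The fits were tested on simulated data with 200 of 19937 genes changed. The noise was normal and independent between genes, with the gene variances that eBayes estimated from these arrays. In these data limma recovered 95.5% of changes of 0.5 on the log2 scale and 100% of those of 1 and 2, with 13 false calls. Smaller changes, a larger share of changed genes and noise shared between genes were not simulated for these fits, so the figures do not extend to them. The chow group that the labels describe is not analysed here.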

Results

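Liver RNA of male C57BL/6 mice, an inbred laboratory strain, was profiled on 6 Affymetrix Mouse Gene 1.0 ST arrays, which measure each transcript with a set of short probes. For all 6 arrays the labels give an age of 6 weeks and 1 week of acclimatization. The mice of 1 group were fed chow with 1% cholesterol (3 arrays, CH1 to CH3). The mice of the other group were fed chow with lovastatin at 100 mg and ezetimibe at 21 mg per 100 g (3 arrays, LE1 to LE3). Lovastatin blocks an early enzyme of cholesterol synthesis, and ezetimibe blocks the uptake of cholesterol from the intestine, so the comparison sets a diet that supplies cholesterol against one that limits it. The labels also describe a chow group, which is not analysed here, so no value below says how either diet compares with chow. The deposited intensities had medians between 158 and 163 on the 6 arrays. Fold changes are given as lovastatin and ezetimibe over cholesterol on the log2(intensity + 1) scale, with standard errors and n = 3 arrays per group.

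The arrays of each diet resembled each other more than those of the other diet. Pearson's r across genes, which are not independent replicates, was 0.9965 to 0.9973 among the cholesterol arrays, 0.9969 to 0.9978 among the lovastatin and ezetimibe arrays and 0.9898 to 0.9911 between the groups. The first principal component held 65.8% of the variance and separated the diets, with scores of -17.56 to -16.67 for the cholesterol arrays and 16.19 to 18.15 for the others. The labels call the arrays biological replicates but do not tie them to single animals, and p-values measure the spread between these 3 arrays per diet, which may be partly technical.

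With lovastatin and ezetimibe, the genes of cholesterol synthesis rose the most. Sqle, the squalene epoxidase, rose 45.3-fold (log2 5.50, SE 0.06) and Cyp51, which demethylates lanosterol, rose 19.6-fold (log2 4.29, SE 0.06). Of the other fixed lists, 16 of 23 fatty acid and triglyceride synthesis genes, 13 of 17 interferon-response genes and 13 of 15 macrophage markers rose, and 10 of 15 genes expressed more in male than in female liver fell, while 2 genes of the first list fell and 2 of the last rose. These 4 list calls were lost when the correlation was estimated (adjusted p = 0.165, 0.146, 0.146 and 0.146 with an estimated correlation). The 12 genes with the highest fold change held 8 members of the cholesterol synthesis list: Sqle, Cyp51, Idi1 (log2 3.76), Lss (3.73), Mvd (3.66), Msmo1 (3.62), Pmvk (3.38) and Hmgcs1 (3.29). The others were Chrna4, a subunit of the nicotinic acetylcholine receptor, at 28.7-fold (log2 4.84, SE 0.11), the stearoyl-CoA desaturase Scd2 at 11.4-fold (3.51, SE 0.06), the retinol dehydrogenase Rdh11 at 11.3-fold (3.50, SE 0.08) and the membrane protein gene Pdzk1ip1 at 9.43-fold (3.24, SE 0.10).

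The 12 genes that fell the most changed less. Adam11, of a family of membrane-bound metalloprotease-like proteins, was 5.41-fold lower (log2 -2.43, SE 0.07) and Arrdc3, an arrestin-domain protein, was 3.97-fold lower (log2 -1.99, SE 0.06). The monooxygenase gene Moxd1 fell by 1.80 on the log2 scale (SE 0.15), and the carboxylesterase genes Ces1e and Ces1b fell by 1.73 and 1.51. The Ces1 genes have near-identical copies that can hybridise to the same probes, so which copy changed is uncertain. The remaining genes were the small nucleolar RNA Snord118 (-1.61, SE 0.24), the carbonic anhydrase Car14 (-1.56), the peroxisomal thiolase Acaa1b (-1.56), the dicarboxylate transporter Slc13a2 (-1.52), the transcription factor gene Srebf1 (-1.44), the signalling inhibitor Spry4 (-1.39) and the fatty acid binding protein Fabp2 (-1.38). The spread of Snord118 was wide in the lovastatin and ezetimibe group (SD 0.57, n = 3). All 24 genes were past the threshold in every alternative run gene by gene.

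**Figure D1:**
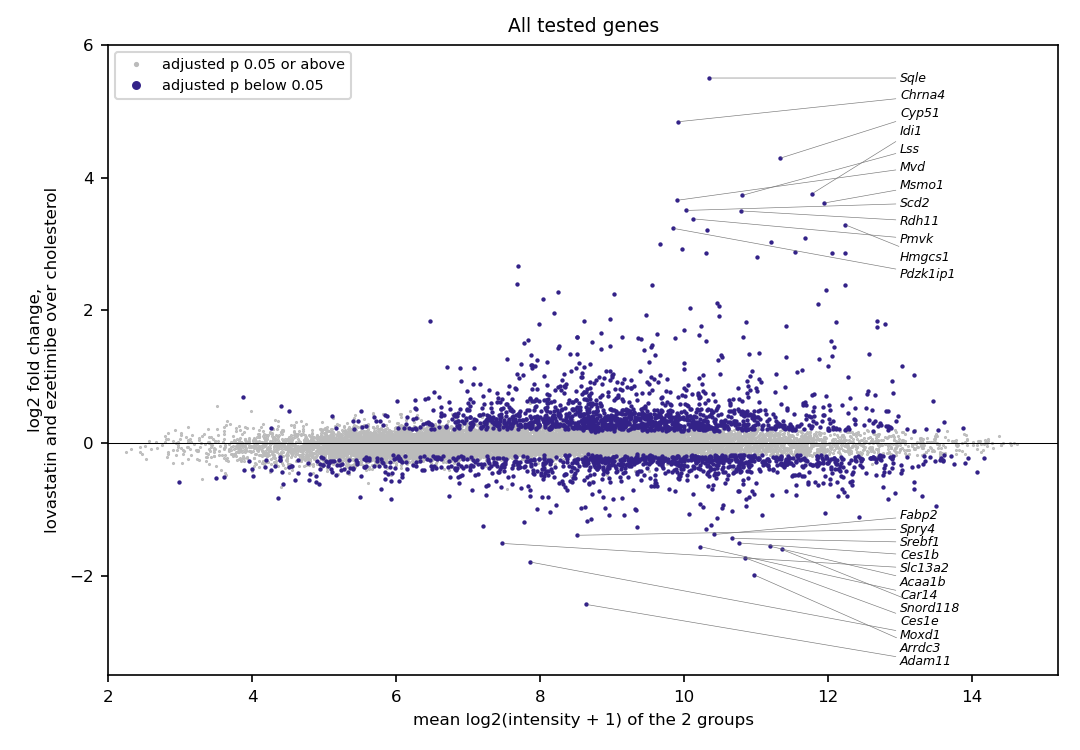
Each point is 1 of the 19937 tested genes, with the mean log2(intensity + 1) of the 2 diets on the horizontal axis and the log2 fold change of lovastatin and ezetimibe over cholesterol on the vertical axis. Dark points are past an adjusted p of 0.05, and lines join names to the 12 genes with the highest and the 12 with the lowest fold change past it, from Sqle at 5.50 to Adam11 at -2.43.

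Of 19937 genes, 2413 (12.1%) passed limma's test at a Benjamini-Hochberg adjusted p below 0.05, 1399 higher and 1014 lower with lovastatin and ezetimibe. At least 1.5-fold changes were found for 436 of them, 316 higher and 120 lower, and at least 2-fold changes for 154, 125 higher and 29 lower. The values of all 3 arrays of a diet lay above those of the other for 6109 genes (30.6%), where chance gives 10%. The share of higher genes among the calls, 58.0%, depended on the scaling: after quantile normalisation it was 47.7% (1460 higher, 1598 lower) and after centring each array on its median 48.4% (1215 higher, 1295 lower). Among calls of at least 1.5-fold the share was 72.5%, against 70.1% after quantile normalisation and 69.1% after centring. Leaving out CH1 or LE2 lowered the calls to 1489 and 1514, and the lower genes alone fell to 551 without CH1, 612 without CH3 and 525 without LE2.

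Each of the 17 measured enzymes of cholesterol synthesis rose, and all 17 passed when adjusted over the list alone. The median rise was 9.23-fold (log2 3.21), from 0.99 for Ebp, a sterol isomerase named here after its value was seen, to 5.50 for Sqle. Idi1, which interconverts the isoprenoid building blocks, went from a mean log2 level of 9.90 (SD 0.09, n = 3) to 13.66 (SD 0.09, n = 3), and Lss, which closes the sterol ring system, from 8.94 (SD 0.07, n = 3) to 12.67 (SD 0.03, n = 3). As a set the enzymes were higher than the other genes (camera adjusted p = 2.15e-43). This was the list of the 35 tested whose call held with an estimated correlation (adjusted p = 0.0038 with an estimated correlation).

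**Figure D2:**
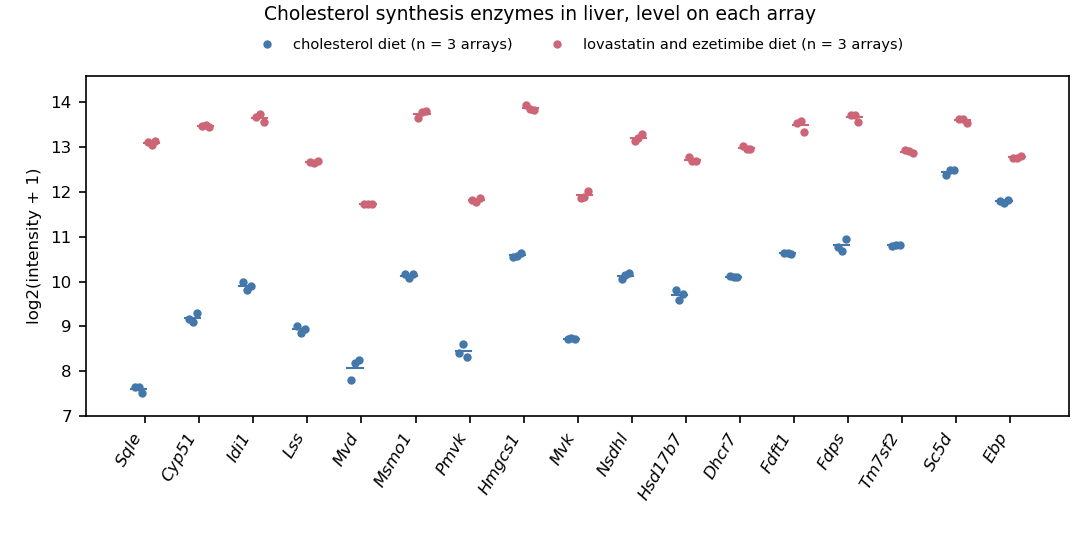
Level of the 17 measured cholesterol synthesis enzymes as log2(intensity + 1) on each array, with 3 cholesterol arrays in blue and 3 lovastatin and ezetimibe arrays in red, and a bar at each group mean. For each enzyme every red point lies above every blue point, with Sqle at 7.60 and 13.10 and Ebp, at the right, with the smallest difference, 0.99.

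Genes of sterol uptake, trafficking and sensing also rose, with 7 of 10 measured members higher, 0 lower and 3 not past the test. Adjusted over the list alone, 7 passed. Stard4, a sterol carrier, rose 4.32-fold (log2 2.11, SE 0.06), Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, 3.47-fold (1.79, SE 0.05), Srebf2, the transcription factor that drives sterol genes, 3.40-fold (1.77, SE 0.05) and Tmem97, a sterol-binding protein, 2.54-fold (1.34, SE 0.05). Npc1l1, the sterol transporter that ezetimibe binds, rose by 0.25 (SE 0.06, adjusted p = 0.027). Its call ended without CH1, CH3, LE1 or LE3 (adjusted p 0.0732 to 0.102, and 0.0075 to 0.102 over all alternatives). The list was higher by camera (adjusted p = 4.81e-08; adjusted p = 0.153 with an estimated correlation). After quantile normalisation, with limma's intensity trend or with a test in the manner of cyberT, 1 member fell.

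In fatty acid and triglyceride synthesis, 16 of 23 genes rose, 2 fell and 5 did not pass, and 20 passed when adjusted over the list alone. The median change was log2 1.02 (2.03-fold). Scd2 rose the most, followed by Acss2, which makes acetyl-CoA from acetate, at 5.20-fold (log2 2.38, SE 0.05), Acly, which makes it from citrate, at 4.94-fold (2.30, SE 0.05), Lpin1, a phosphatidate phosphatase, at 3.38-fold (1.76, SE 0.05) and the fatty acid synthase Fasn at 3.37-fold (1.75, SE 0.05). Srebf1, a transcription factor of fatty acid synthesis, fell by 1.44 (SE 0.05) while these genes rose. The list was higher by camera (adjusted p = 1.40e-14; adjusted p = 0.165 with an estimated correlation). With limma's intensity trend and robust prior, 4 genes fell rather than 2.

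Genes regulated by the oxysterol receptor LXR went both ways, with 2 of 16 higher, 6 lower and 8 not past the test. Adjusted over the list alone, 9 passed. Pltp, the phospholipid transfer protein, rose 6.97-fold (log2 2.80, SE 0.05), whereas Srebf1, the lipoprotein lipase Lpl (-1.27, SE 0.06), the apolipoprotein gene Apoc1 (-0.30, SE 0.05) and the sterol exporter Abca1 (-0.28, SE 0.05) fell. The canalicular and intestinal sterol exporters Abcg5 (-0.14, SE 0.05, adjusted p = 0.136) and Abcg8 (0.00, SE 0.05, adjusted p = 0.983) did not pass. For Abcg5 the adjusted p was 0.0300 after quantile normalisation, 0.0038 with limma's intensity trend and 0.0084 with the test in the manner of cyberT. The list was lower by camera (adjusted p = 0.0389; adjusted p = 0.750 with an estimated correlation), a call that ended without CH1 (0.0530), CH3 (0.107) or LE1 (0.0966).

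Bile acid genes were divided too, with 4 of 23 higher, 9 lower and 10 not past the test, and 14 passed when adjusted over the list alone. Slco1a4, an organic anion transporter, rose 2.54-fold (log2 1.34, SE 0.05) and Cyp8b1, the sterol 12-hydroxylase, 1.67-fold (0.74, SE 0.05). Cyp7b1, of the alternative bile acid pathway, fell by 0.66 (SE 0.05) and the transporter Slco1a1 by 0.63 (SE 0.06). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 0.23 (SE 0.05, adjusted p = 0.023), a call lost without any array but LE3 (adjusted p 0.0607 to 0.0951, and 2.92e-05 to 0.0951 over all alternatives). The list's camera call (lower, adjusted p = 0.0389; adjusted p = 0.750 with an estimated correlation) was lost after centring (0.0689) and without CH1 (0.101), CH3 (0.108) or LE1 (0.0929). The number of lower genes was 4 without CH1 and 5 without CH3, LE1 or LE2.

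In lipoprotein assembly and sterol storage, 3 of 14 genes rose, 0 fell and 11 did not pass, and 3 passed when adjusted over the list alone. Apoa4, an apolipoprotein of triglyceride-rich particles, rose 2.72-fold (log2 1.45, SE 0.05) and the lipid droplet protein Plin2 1.20-fold (0.26, SE 0.05). Apoa5 rose by 0.25 (SE 0.05, adjusted p = 0.020), but not without any 1 array other than LE2 (adjusted p 0.0505 to 0.0727, and 2.68e-05 to 0.0727 over all alternatives). With the intensity trend 5 rose and 2 fell, with the test in the manner of cyberT 5 rose and 1 fell, and after quantile normalisation 1 fell. The list was not called (camera adjusted p = 0.127).

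Markers of Kupffer cells and other macrophages rose, 13 of 15 with 0 lower and 2 not past the test, and 13 when adjusted over the list alone. The median change was 1.29-fold (log2 0.37). Cd68, a lysosomal protein of macrophages, rose by 0.55 (SE 0.05), the haemoglobin scavenger receptor Cd163 by 0.50 (SE 0.07), the lysozyme gene Lyz2 by 0.48 (SE 0.05) and the complement gene C1qb by 0.47 (SE 0.05). The list was higher by camera (adjusted p = 2.30e-11; adjusted p = 0.146 with an estimated correlation). Markers of lipid-associated macrophages rose in 5 of 9 cases with 0 lower and 4 not past the test, and 6 passed when adjusted over the list alone (median log2 0.24; camera adjusted p = 1.12e-04; adjusted p = 0.139 with an estimated correlation). Fabp5, a fatty acid binding protein, rose 3.75-fold (log2 1.91, SE 0.05) and the tetraspanin Cd9 1.40-fold (0.48, SE 0.08). The elastase Mmp12 (0.40, SE 0.09) and the tetraspanin Cd63 (0.27, SE 0.07) lost their calls in several settings, Mmp12 without CH1, CH3, LE2 or LE3 (adjusted p 0.0703 to 0.117, and 0.0069 to 0.117 over all alternatives) and Cd63 after quantile normalisation (0.0778), after centring (0.0696) and without any array but LE1 (0.0981 to 0.143, and 0.0112 to 0.143 over all alternatives). The number of higher genes in this list was 2 without CH1 or LE2 and 3 without CH2, CH3 or LE3.

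Of 17 interferon-response genes, 13 rose, 0 fell and 4 did not pass, with 14 past the test when adjusted over the list alone. The median change was 1.43-fold (log2 0.51), beside a median of log2 0.37 for the macrophage markers. Usp18, which removes the ubiquitin-like ISG15, rose 1.96-fold (log2 0.97, SE 0.06), the chemokine Cxcl10 1.80-fold (0.85, SE 0.08), the antiviral protein gene Rsad2 1.75-fold (0.81, SE 0.08) and the transcription factor Irf7 1.65-fold (0.72, SE 0.07). The list was higher by camera (adjusted p = 4.00e-13; adjusted p = 0.146 with an estimated correlation). Of 17 lysosome genes, 5 rose, 1 fell and 11 did not pass, with 9 past the test when adjusted over the list alone. Their median was log2 0.12, beside 0.37 for the macrophage markers. The protease gene Ctsd rose by 0.53 (SE 0.05), the galactosidase gene Gla by 0.46 (SE 0.06) and Grn, the progranulin gene, by 0.33 (SE 0.06), while the protease gene Ctsb fell by 0.31 (SE 0.05). The lysosome call (adjusted p = 0.0163; adjusted p = 0.750 with an estimated correlation) was lost without the dimmest 33.3% of genes (0.0598), and 3 genes rose without CH1, CH2 or LE2 and 8 with the intensity trend or the test in the manner of cyberT. In these last settings, after quantile normalisation and without the dimmest 33.3% of genes, 2 lysosome genes fell.

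Genes expressed more in male than in female mouse liver were lower in these male mice on lovastatin and ezetimibe. Of 15, 10 fell, 2 rose and 3 did not pass, and 12 passed when adjusted over the list alone (median log2 -0.58). Besides Moxd1, Hsd3b5, a hydroxysteroid dehydrogenase, was 2.18-fold lower (log2 -1.12, SE 0.05), the pheromone carrier gene Mup21 2.11-fold (-1.08, SE 0.10) and the glucuronosyltransferase gene Ugt2b1 1.61-fold (-0.69, SE 0.06). The last 3 belong to families of near-identical copies, and signal from other copies cannot be ruled out for them. The number of higher genes was 1 after centring or when any 1 array was left out. The list was lower by camera (adjusted p = 2.37e-08; adjusted p = 0.146 with an estimated correlation). Of 11 female-biased genes, 3 rose, 0 fell and 8 did not pass, and 3 passed when adjusted over the list alone. The camera call (higher, adjusted p = 0.0065; adjusted p = 0.317 with an estimated correlation) rested on Abcd2, a peroxisomal fatty acid transporter (3.87-fold, log2 1.95, SE 0.06), Cyp17a1, a steroid hydroxylase (3.66-fold, 1.87, SE 0.05), and Cyp2b9, a drug-metabolising enzyme with near-identical copies (2.18-fold, 1.13, SE 0.15), and the list's median was 0.04.

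Genes of fatty acid oxidation and targets of the fatty acid receptor PPAR alpha went both ways, 4 of 21 higher, 8 lower and 9 not past the test, and 17 passed when adjusted over the list alone (median log2 -0.16). Pdk4, a kinase that inhibits pyruvate oxidation, rose 2.96-fold (log2 1.56, SE 0.05), whereas the thiolase Acaa1b, the acyl-CoA thioesterase Acot1 (-0.71, SE 0.06) and the pantetheinase Vnn1 (-0.69, SE 0.05) fell. The list was lower by camera (adjusted p = 0.0104; adjusted p = 0.750 with an estimated correlation). The number of higher genes was 2 without any 1 array, and that of lower genes 3 without CH1 or LE2, 4 without CH3 and 5 without CH2 or LE1, against 13 with the intensity trend or the test in the manner of cyberT.

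Oxidative phosphorylation genes were slightly lower: 14 of 66 fell, 0 rose and 52 did not pass, and 21 passed when adjusted over the list alone (median log2 -0.11). The respiratory chain genes Ndufa1 (-0.45, SE 0.07), Ndufb3 (-0.36, SE 0.07), Sdhb (-0.34, SE 0.05) and Ndufa4 (-0.29, SE 0.08) changed the most. Ndufb3 did not pass without CH3 (adjusted p = 0.0571, and 6.10e-04 to 0.0571 over all alternatives), and Ndufa4 did not pass after quantile normalisation (0.0733) or without any 1 array (0.0511 to 0.120, and 0.0027 to 0.120). The list was lower by camera (adjusted p = 4.81e-08; adjusted p = 0.139 with an estimated correlation). The number of lower genes was 5 without CH1 or LE2, 8 without CH2, 4 without CH3 and 7 without LE1, and 22 after quantile normalisation or without the dimmest 33.3% of genes, 31 with the intensity trend and 27 with the test in the manner of cyberT.

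Of 23 cell cycle genes, 6 fell, 0 rose and 17 did not pass, and 8 passed when adjusted over the list alone (median log2 -0.16). Birc5, a mitotic survival factor, fell by 0.47 (SE 0.07), the cyclins Ccnb2 and Ccne1 by 0.37 (SE 0.06) and 0.33 (SE 0.05), and the kinase Cdk1 by 0.31 (SE 0.06). Cdk1 did not pass without CH3, LE2 or LE3 (adjusted p 0.0534 to 0.0657, and 0.0031 to 0.0657 over all alternatives), and the count was 3 without CH3 or LE2. The list was lower by camera (adjusted p = 1.23e-04; adjusted p = 0.168 with an estimated correlation).

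Among circadian genes, 3 of 17 rose, 6 fell and 8 did not pass, and 10 passed when adjusted over the list alone. The clock repressor Ciart rose 2.24-fold (log2 1.16, SE 0.15) and the clock gene Per1 1.47-fold (0.55, SE 0.06), while the clock output factor Dbp was 2.01-fold lower (-1.01, SE 0.06) and the repressor Bhlhe41 1.80-fold lower (-0.84, SE 0.10). The hour of sampling is not given in the labels. The list was not called (camera adjusted p = 0.0970), but was after quantile normalisation (0.0457) and without LE3 (0.0460).

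Zonated hepatocyte genes changed in both directions. Of 12 pericentral genes, 4 rose, 1 fell and 7 did not pass, and 5 passed when adjusted over the list alone (camera adjusted p = 0.207, not called). The ammonium transporter Rhbg rose by 0.47 (SE 0.06), the Wnt-enhancing receptor Lgr5 by 0.35 (SE 0.05) and the glutamine synthetase Glul by 0.27 (SE 0.06). Cyp2c37, which has near-identical copies, fell by 0.35 (SE 0.07). Glul did not pass without CH1, CH2, LE2 or LE3 (adjusted p 0.0692 to 0.113, and 1.34e-04 to 0.113 over all alternatives), and 2 genes rose without any of these 4. Of 9 periportal genes, 1 rose, 4 fell and 4 did not pass, and 5 passed when adjusted over the list alone (camera lower, adjusted p = 0.0194; adjusted p = 0.750 with an estimated correlation). The urea cycle gene Otc fell by 0.63 (SE 0.05), the histidine-degrading Hal by 0.34 (SE 0.05) and the aldehyde dehydrogenase Aldh1b1 by 0.31 (SE 0.05), while the lipid droplet protein Hsd17b13 rose by 0.31 (SE 0.06), except without CH1 (adjusted p = 0.0613, and 2.63e-05 to 0.0613 over all alternatives).

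Xenobiotic, antioxidant and stress lists held single strong changes but were not called as lists. Of 23 targets of the xenobiotic receptors CAR and PXR, 9 rose, 3 fell and 11 did not pass, and 17 passed when adjusted over the list alone (camera adjusted p = 0.217). Cyp2c55 rose 2.33-fold (log2 1.22, SE 0.05), Cyp2b9 2.18-fold, Aldh1a7 1.59-fold (0.67, SE 0.05) and the drug exporter Abcb1a 1.42-fold (0.51, SE 0.10). Abcb1a did not pass without LE3 (adjusted p = 0.0655, and 4.64e-04 to 0.0655 over all alternatives). The count of lower genes was 5 after quantile normalisation or with a pseudocount of 16, 6 without the dimmest 33.3% of genes and 7 with the intensity trend or the test in the manner of cyberT. Of 15 targets of the antioxidant regulator NRF2, 4 rose, 2 fell and 9 did not pass, and 7 passed when adjusted over the list alone (camera adjusted p = 0.316). Srxn1, which repairs peroxiredoxins, rose 2.03-fold (1.02, SE 0.05), Ugdh 1.68-fold (0.75, SE 0.05) and Nqo1 1.33-fold (0.41, SE 0.05), and the epoxide hydrolase Ephx1 fell by 0.48 (SE 0.05). The count of lower genes was 1 without any array but LE3.

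Of 19 genes of the unfolded protein and integrated stress responses, 5 rose, 1 fell and 13 did not pass, and 9 passed when adjusted over the list alone (camera adjusted p = 0.207, median log2 -0.01, mean 0.15). Asns, the asparagine synthetase, rose 2.12-fold (log2 1.08, SE 0.07), and the transcription factors Atf3 and Atf4 rose 1.76-fold (0.81, SE 0.12) and 1.65-fold (0.72, SE 0.05). Creld2, of the endoplasmic reticulum, rose 1.33-fold (0.42, SE 0.06). The count of lower genes was 2 after quantile normalisation, centring, leaving out the dimmest 33.3% of genes, with the intensity trend or with the test in the manner of cyberT.

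Of 12 genes of gluconeogenesis and glycolysis, 2 rose, 2 fell and 8 did not pass, and 4 passed when adjusted over the list alone (camera adjusted p = 0.852, median log2 -0.01, mean 0.16). Igfbp1, an insulin-repressed binding protein, rose 3.02-fold (log2 1.59, SE 0.05) and the coactivator Ppargc1a 1.95-fold (0.97, SE 0.07). The gluconeogenic enzyme Fbp1 (-0.27, SE 0.05) did not pass without CH1 or LE2 (adjusted p 0.0533 to 0.0595, and 2.39e-06 to 0.0595 over all alternatives), and the transcription factor Foxo1 (-0.23, SE 0.05) did not without any array but LE3 (0.0737 to 0.123, and 0.0019 to 0.123). In this list 4 genes were lower with the intensity trend or the test in the manner of cyberT. Of 23 acute-phase genes, 3 rose, 4 fell and 16 did not pass, and 8 passed when adjusted over the list alone (camera adjusted p = 0.672). The iron-siderophore binder Lcn2 rose 1.99-fold (log2 0.99, SE 0.06), and Saa1 (-0.63, SE 0.08), Saa3 (-0.58, SE 0.07) and Orm3 (-0.58, SE 0.05), which have near-identical copies, fell. With the intensity trend, 5 rose.

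In the autophagy machinery, which degrades cell components in the lysosome, 1 of 32 genes rose, 3 fell and 28 did not pass (camera adjusted p = 0.460). Adjusted over the list alone, 6 passed. Of all 19937 tested genes 12.1% passed, a share near that of this list. An unadjusted p under 0.05 by limma was found for 13 of the 32, beside 4941 of all tested genes. Atg16l2 rose 1.59-fold (log2 0.67, SE 0.05) and Atg5, of the conjugation step, fell by 0.31 (SE 0.05). Ulk2, an initiating kinase, was at -0.20 (SE 0.05) and passed only with all 6 arrays (adjusted p 0.0692 to 0.115 without any 1, and 0.0015 to 0.115 over all alternatives). Gabarapl2 was at -0.20 (SE 0.05) and did not pass as a mean of probe sets (0.0900) or without any array but LE3 (0.0877 to 0.126, and 3.78e-04 to 0.126). Map1lc3b, the precursor of the autophagosome protein LC3B, was at 0.22 (SE 0.06, adjusted p = 0.052) and did not pass. It passed after quantile normalisation (0.0261), without the dimmest 33.3% of genes (0.0179), as a mean of probe sets (0.0478), with the intensity trend (9.80e-04), with the test in the manner of cyberT (0.0043) and with a pseudocount of 16 (0.0338). The LC3 proteases Atg4b (0.16, SE 0.06, adjusted p = 0.147) and Atg4d (-0.02, SE 0.06, adjusted p = 0.910) did not pass. The count of lower genes was 1 without any array but LE3, 5 after centring, 6 without the dimmest 33.3% of genes, 7 after quantile normalisation or with the test in the manner of cyberT and 8 with the intensity trend, and that of higher genes was 2 without LE3, after quantile normalisation, as a mean of probe sets or with a pseudocount of 16, and 3 without the dimmest 33.3% of genes, with the intensity trend or with the test in the manner of cyberT.

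None of 50 cytosolic ribosomal protein genes passed limma's test, and 2 had an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.226, and 0.0245 without LE2), with Rpl38 at -0.16 (SE 0.06, adjusted p = 0.158) and Rps29 at -0.15 (SE 0.06, adjusted p = 0.170). With the intensity trend 2 ribosomal genes rose and 4 fell, and with the test in the manner of cyberT 1 rose and 2 fell.

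Of the 13 cell type lists, 10 were not called. Among 13 sinusoidal endothelial markers 0 passed limma's test and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.460), with Fcgr2b at -0.13 (SE 0.05, adjusted p = 0.130) and Stab2 at -0.12 (SE 0.05, adjusted p = 0.151), and 3 fell after quantile normalisation or with the intensity trend and 1 with the test in the manner of cyberT. Among 14 stellate cell and fibroblast markers 1 passed, the collagen gene Col3a1 (-0.19, SE 0.05), but not with the test in the manner of cyberT (adjusted p = 0.0567) or without any 1 array (0.0669 to 0.147, and 0.0126 to 0.147 over all alternatives; camera adjusted p = 0.852). None of 8 cholangiocyte markers passed and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.858), with the chloride channel Cftr at -0.34 (SE 0.09, adjusted p = 0.052, and 0.0202 without LE3, 0.0377 after centring, 0.0454 with the intensity trend and 0.0459 with a pseudocount of 16, in a range of 0.0202 to 0.163 over all alternatives) and Epcam at -0.08 (SE 0.05, adjusted p = 0.436). Among 8 B and plasma cell markers 1 passed, Mzb1 (0.30, SE 0.08), but not after quantile normalisation (adjusted p = 0.0677), after centring (0.0618) or without any 1 array (0.0666 to 0.126, and 0.0138 to 0.126 over all alternatives; camera adjusted p = 0.988).

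None of 12 T and NK cell markers passed limma's test and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.895), with Cd4 at -0.18 (SE 0.05, adjusted p = 0.071) and Nkg7 at 0.24 (SE 0.10, adjusted p = 0.184), and none of 11 neutrophil markers passed, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.603), with Elane at -0.24 (SE 0.07, adjusted p = 0.078) and Retnlg at -0.18 (SE 0.06, adjusted p = 0.111). Of 4 erythroid markers 1 fell, the haem synthesis gene Alas2, by 0.82 (SE 0.05; camera adjusted p = 0.217). None of 9 pancreatic acinar markers passed, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.701; Ctrb1 at 0.22, SE 0.11, and Cela2a at 0.17, SE 0.09), and none of 7 adipocyte markers, with 3 (camera adjusted p = 0.896; Retn at 0.18, SE 0.05, and Plin4 at -0.18, SE 0.06). Single members passed in other settings: 1 of the T and NK cell markers fell after either scaling or without the dimmest 33.3% of genes, 1 of the neutrophil markers fell in the same settings and 1 rose without CH2, and 1 adipocyte marker fell in the same settings. Retn rose without LE3 (adjusted p = 0.0461) and without the dimmest 33.3% of genes (0.0287), in a range of 0.0287 to 0.212 over all alternatives. Adjusted over the list alone, 1 B and plasma cell marker and 1 erythroid marker passed, and 0 passed in the endothelial, stellate, cholangiocyte, T and NK cell, neutrophil, pancreatic and adipocyte lists. The median and the camera direction differed in sign for the stellate list (0.01, lower) and the cholangiocyte list (0.03, lower), and for the B and plasma cell list the median was -0.05 and the mean 0.01.

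**Figure D3:**
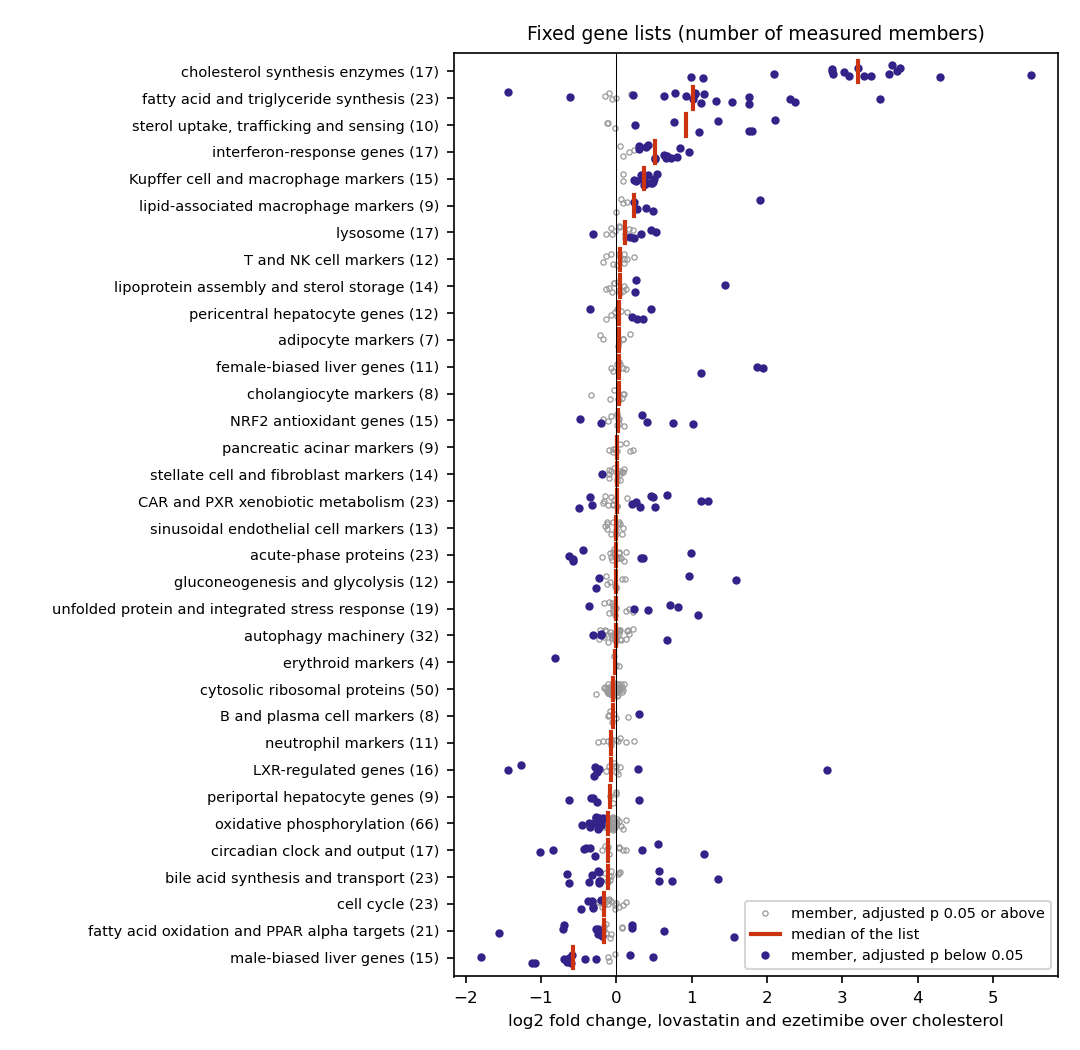
Log2 fold change of lovastatin and ezetimibe over cholesterol for each measured member of 34 of the 35 fixed gene lists, sorted by list median, with the number of members in parentheses and random vertical scatter within a list. Filled points are past an adjusted p of 0.05, open points are not, and red bars are list medians, from 3.21 for cholesterol synthesis to -0.58 for male-biased genes.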

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

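The test by other splits of the arrays was chosen before its result was seen. The probe sets left out of the comparison also carried differences between the diets. For these counts the limma test was run and adjusted over all 35556 probe sets rather than over the 19937 genes, and 1995 (5.6%) passed. Of the 12146 probe sets with no gene name, 345 (2.8%) passed the threshold, a smaller share. Among these, 149 were higher and 196 lower with lovastatin and ezetimibe. Of the 1621 probe sets assigned to several genes, 113 (7%) passed, 57 higher and 56 lower. The genes behind them were not named, since the annotation gives none or several. No test for single outlying arrays was made within the groups of 3.

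Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many genes past the threshold as the diets did, the split by diet itself with 2413 genes, and the highest of the others gave 0 by limma (337 to 1295 genes at an unadjusted p under 0.05, against 4941). With 10 splits the share cannot go below 0.1, so the splits are too few for a share under 0.05. Each of the other splits also mixes the diets, so the difference between diets adds to the spread within its groups and lowers its calls. Their counts therefore do not show what chance alone would give, and the splits cannot decide.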

How the results depend on the processing

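All alternatives were chosen before the data were examined. Leaving aside every probe set and the 1.5-fold limit, which were applied to counts only, calls shared with those reported had the same sign in each alternative. Of 182 genes followed singly, those of the naming rule, the large changes outside the lists and the test sets, not all of them named in the text, 153 passed, 130 of them under these alternatives, 23 were lost under at least 1, and 15 that did not pass did so under at least 1. Cftr was at 0.0257 with the replicate block. The genes past the threshold (2413) were 436 at a 1.5-fold limit (316 higher, 120 lower) and 1489 to 1868 with 1 array left out, of which 525 to 893 were lower. The lower genes (1014) were 1598 after quantile normalisation and 1560 with the intensity trend. The cause of these shifts was not tested, except that a left-out array leaves fewer samples.

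With an estimated correlation 1 of the 15 called lists stayed called. Camera's p also rose where the estimated correlation lay below the preset 0.01. For cholesterol synthesis (correlation -0.01) the unadjusted p went from 6.15e-45 to 1.10e-04. For lipid-associated macrophages (-0.049) it went from 2.56e-05 to 0.0119. The losses can therefore not be put down to correlation between genes alone. The adjusted p was 0.153 for sterol uptake, 0.165 for fatty acid synthesis, 0.750 for LXR-regulated, bile acid, lysosome, fatty acid oxidation and periportal genes, 0.146 for interferon-response, male-biased and macrophage genes, 0.139 for oxidative phosphorylation and lipid-associated macrophages, 0.168 for cell cycle and 0.317 for female-biased genes. With 1 array left out the LXR list ran from 0.0227 to 0.107 and the bile acid list from 0.0250 to 0.108, and the bile acid list was at 0.0689 after centring. The lysosome list was at 0.0598 without the dimmest 33.3% of genes.

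The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.021, -0.097 and 0.160 across genes. Between differently numbered arrays the correlations ran from -0.228 (CH3 and LE1) to 0.246 (CH2 and LE1). Whether such arrays shared a source of variation across the diets was not tested. With a replicate block 1688 genes passed, 657 of them lower, and the LXR and bile acid lists had an adjusted p of 0.0626 and 0.0594.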

Other observations

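The tests of other cell types, of the interferon excess over macrophages, of the LXR targets, of hepatocyte RNA loss and of multigene families were chosen after the result was seen. The reading of the LXR test was also tightened after its value was known, to the more cautious one, and the members outside multigene families were narrowed after a first value was known, leaving out genes of the Slco1a and Selenbp families.

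The genes outside the lists described first were chosen after their values were seen, by size of change outside the 35 lists and outside the 24 genes of largest change. In all, 11 such genes were at least 4-fold higher with lovastatin and ezetimibe and 13 at least 2-fold lower. Mfsd2a, a transporter of lysophospholipids, rose 8.02-fold (95% interval 2.82 to 3.19 on the log2 scale, n = 3 per group), the glycolytic aldolase Aldoc 7.58-fold (2.92, SE 0.06), Aacs, which activates acetoacetate for lipid synthesis, 7.30-fold (2.87, SE 0.05) and the phosphatase-like gene Mtmr11 6.32-fold (2.66, SE 0.06). The others were Sytl5 (2.39), Pstpip2 (2.38), Nfe2 (2.28), Cib3 (2.24), Defb1 (2.17), Esyt2 (2.06) and Dpysl2 (2.04). The lower genes were Hsd3b2 (-1.30), Obp2a (-1.25), Ppm1k (-1.24), Capn8 (-1.19), 9130409I23Rik (-1.17), Serpina12 (-1.14), Socs2 (-1.13), Tk1 (-1.09), Etnppl (-1.08), Car1 (-1.08), Upp2 (-1.05), Derl3 (-1.04) and Fitm1 (-1.03). Socs2 is a feedback inhibitor of growth hormone signalling, and Ppm1k activates the breakdown of branched-chain amino acids.

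Of 15 macrophage markers (median log2 0.37) and 17 interferon-response genes (0.51), 13 each were higher with lovastatin and ezetimibe, and 0 genes of either list were in another list. Both camera calls were lost with an estimated correlation (adjusted p = 0.146 for each). A lower share of hepatocyte RNA would raise the markers of all other cell types, but endothelial, stellate and bile duct markers had a pooled median of 0.01 (95% bootstrap interval -0.07 to 0.05), against 0.37. Bootstrap intervals here and below resampled the genes of a set, which are not independent, and hold no spread between arrays. A second set of 12 macrophage genes, fixed before its values were seen, had a median of 0.25 (0.13 to 0.34). More macrophage RNA is therefore a candidate explanation, although not every gene of the set passed. Cybb, Fcer1g, Axl, Tyrobp, Folr2 and Ly86 passed as higher. Tyrobp, Folr2 and Ly86 lost their calls when certain single arrays were left out. Aif1, Ms4a7, Itgam, Cx3cr1 and Mertk did not pass (adjusted p 0.104 to 0.646). Mertk passed as higher without the dimmest 33.3% of genes (0.0447) and with the intensity trend (0.0329). Mpeg1 in that set, singled out after its value was seen, was at -0.17 (SE 0.06, adjusted p = 0.107). Mpeg1 passed as lower after quantile normalisation (0.0194) and without the dimmest 33.3% of genes (0.0458). The same held with the intensity trend (0.0241) and with the test in the manner of cyberT (0.0382). More cells and more RNA per cell were not separated. The interferon median exceeded the macrophage median by 0.14 (-0.12 to 0.33), so whether macrophage RNA alone brought the interferon genes cannot be told apart from a response in other cells, the interval including 0. The abundant macrophage genes C1qb and Lyz2 had mean log2 levels of 10.60 and 10.40 in the cholesterol group and 11.07 and 10.89 in the other, and a diet effect on inflammation stays open and untested.

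Srebf1 fell by 1.44 while 16 of 23 fatty acid synthesis genes rose, and Scd1, singled out after its value was seen, had the same level on both diets (14.43 and 14.44, log2 difference 0.00, SE 0.05, adjusted p = 0.992). The Scd1 level lay 0.53 below the brightest probe set (14.96), between the limits set in advance for a probe set at the ceiling of the array and one clear of it, so a hidden rise cannot be told apart from no change. Of the 30 genes at a log2 level of 14 or more, 2 passed the threshold, at -0.23 and -0.44. Lower LXR activity could account for lower Srebf1, since oxysterols made from cholesterol activate LXR. The targets Abca1, Abcg1, Abcg5, Abcg8 and Mylip had a median of -0.14 (95% bootstrap interval -0.28 to 0). With so few genes the interval only ran from the lowest member, Abca1, to the highest, Abcg8. It cannot decide and leaves this explanation open, and Pltp rose by 2.80. Abcg1 (-0.25, SE 0.05) did not pass without CH1, CH2, LE1 or LE2 (adjusted p 0.0573 to 0.0637, and 0.0024 to 0.0637 over all alternatives).

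Of 15 male-biased liver genes, 10 were lower and 2 higher with lovastatin and ezetimibe (median log2 -0.58). The list's camera call was lost with an estimated correlation (adjusted p = 0.146). A general loss of hepatocyte RNA would lower other hepatocyte genes alike, but lipoprotein and zonated genes had a pooled median of 0.01 (95% bootstrap interval -0.04 to 0.09). Signal shared within multigene families stays open. The 5 members outside them, Moxd1 (-1.80), Cyp7b1 (-0.66), Elovl3 (-0.41), C8b and Susd4, had a median of -0.41 (-1.80 to 0.17). With so few genes the interval only ran from the lowest member, Moxd1, to the highest, Susd4, so it cannot decide. C8b (-0.27) did not pass without CH1, CH3, LE1 or LE2 (adjusted p 0.0589 to 0.0694). Susd4 (0.17) did not pass after centring (0.0810) or without any 1 array (0.0862 to 0.151). Weaker growth hormone signalling may be a cause: 4 of its targets, fixed before their values were seen although Socs2 had been, had a median of -0.23 (-0.65 to 0.49). That median met the limit set in advance for this cause. The targets went both ways, however, and the interval only ran from the lowest, Igfals, to the highest, Cish, so the question stays open. Igfals (-0.65) and Egfr (-0.36) were lower, Cish (0.49) was higher and Igf1 (-0.10) did not pass (adjusted p = 0.0391 with limma's intensity trend). The diets' effect on sex-biased genes by other routes, such as food intake, was not tested.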
